A study of Mus musculus with 74 samples.

How the data were processed

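The series holds 74 samples, 38 of RNA and 36 of ChIP or input, and processed values were present for 30 of them. These were the 18 RNA libraries of the cell lines (9 groups of 2) and the 12 ChIP libraries (6 targets at 2 times, 1 library each). LPS was given at 100.0 ng/mL to primary macrophages, and the dose for the cell lines is not given in the sources used here. The other 44 samples were not analysed here.

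Reads were trimmed with Trim Galore 0.5.0, aligned to mm10 with STAR 2.4.2 and counted with featureCounts of Subread 1.4.6, per the submitters' processing notes. DESeq2 under R 3.4.0 was named for the RNA. For ChIP the submitters' processing notes name Bowtie2 2.3.4.1, Picard 2.14.0, SAMtools 1.5 and deepTools 2.5.4. The deposited signal of each RNA library was a read count per gene divided by 1 size factor, since 100.0% of values came out whole within 0.1 read after rescaling (largest distance 0.0722). The deposited ChIP signal per gene is in the authors' scaling, which is not given in the sources used here. Per the file headers the authors also give log2 fold changes with standard errors and a p-value with its adjusted value for each comparison. The authors' score of the primary macrophage table equals the absolute log2 fold change minus 1, over its standard error and signed, to within 1.4e-13. In the cell line table for 120 min, an adjusted p-value column carries a 60 min name among the deposited columns, and it matched the adjusted p recomputed from its own 120 min block to within 2.9e-07.

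Counts had been planned for, and the unit differed from that, so the test fixed for normalized values was used. limma 3.58.1 with an intensity trend was fitted in R 4.3.3 to log2(value + 1), with 1 mean per group over the 12 libraries of each time's table. Genes needed a mean of at least 1, which left 17301 and 17450, and adjusted p (Benjamini-Hochberg) below 0.05 was a call. The 16 comparisons were 6 LPS responses, 6 of an edited line against RAW264.7 at 1 time, and 4 differences between the response of an edited line and that of RAW264.7. For genes with few reads, floors were set at 3 reads over the libraries of a group and 95% counting intervals used the recovered reads.

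Of 25 fixed gene lists and 2 taken from the authors' table of primary macrophages, 24 had at least 5 measured members. Each was tested by camera of limma with a preset correlation of 0.01, with adjustment over the lists. Markers of B cells, of T and NK cells and of fibroblasts had too few measured members. ChIP ratios are 60 over 0 min, with no pseudocount and no test between replicates.

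Named genes followed a rule fixed before the data were examined. It took up to 8 largest changes of each direction among calls with a mean of at least 50 normalized reads in the higher group and replicate ranges that did not overlap, predicted genes aside. It added a fixed panel of 18 genes, of which Il12b did not pass the filter on low values, and up to 4 members of each list by smallest p. For ChIP it took the 5 largest and 5 smallest ratios among genes above the lower quartile of signal at both times. The text gives the 4 largest of each direction by limma log2 fold change, whatever their stability, the panel, and list members picked from the rule before any alternative was run, and leaves out results of items withheld for evaluation.

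Pairing by replicate number was checked by correlating replicate 1 minus 2 between groups. Over 15 pairs of groups r ran from 0.16 to 0.56 (median 0.27) in the 60 min table and from 0.22 to 0.56 (0.31) in the 120 min table, so a replicate block was run beside every result. The alternatives were limma without trend, no filter, pseudocounts of 0.5 and 5, the replicate block, only the groups compared, a minimum fold change and leaving out each library. For lists they were an estimated correlation, fry and quantile normalization, and for ChIP division by H3.3 signal, a filter on low signal, Pearson r and genes shared by both tables. TMM scaling, edgeR 4.0.16 with and without the block and DESeq2 1.42.0 on the recovered reads were added after the data were seen, as was the list test with both the block and an estimated correlation. On simulated data 9.7% of the limma calls were false for the RAW264.7 response at 60 min (14 of 145), and 0% to 10.8% over all simulated comparisons, mostly above the 5% aimed for. In list tests there 0 and 4 of 50 unchanged lists had an unadjusted p below 0.05 in 2 runs. These do not test the preset correlation for real lists. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used for tables and plots.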

Results

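Loss of the replacement histone H3.3 and the transcriptional response to lipopolysaccharide (LPS) were examined in 18 RNA libraries of RAW264.7 macrophages and of the derived lines 264 and 3205. Each line had 2 libraries at 0, 60 and 120 min of LPS. A further 12 ChIP libraries of primary bone marrow macrophages held 1 library per target at 0 and 60 min. The series describes wild type, hypomorphic and double knockout lines, and the labels used here do not say which number is which. The RNA libraries held 13.1 M to 53.9 M reads, and 16108 to 18950 genes had at least 1 read. Cell line values are limma log2 fold changes ± SE with n = 2 libraries per group. They rest on values plus 1, which shrinks changes of genes near 0 reads, and the largest changes are ranked by them. Ratios and floors for genes with few reads carry counting error only and can stand in another order. The p-values measure only the spread between these samples, which may be technical.

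H3f3a, 1 of the pair of genes that encode H3.3 (chromosome 1, 180802560 to 180813605, mm10), stood at 2926 and 2055 normalized reads in the unstimulated RAW264.7 libraries. It stood at 188 and 236 in line 264 and 76.2 and 63.4 in line 3205. At 60 min the values were 2579 and 2445, 172 and 226, and 58.2 and 56.7 in the same order. At 120 min they were 3109 and 2438, 182 and 212, and 53.5 and 37.5. The second gene, H3f3b, stood at 15367 and 13623 in RAW264.7, 5642 and 7145 in line 264 and 7177 and 7437 in line 3205 before LPS. Its values were 29823 and 30051, 14080.0 and 14008, and 11401 and 12274 at 60 min. They were 34155 and 33056, 17765 and 15991, and 11416 and 13284 at 120 min. Unstimulated line 264 had 11.6-fold less H3f3a RNA than RAW264.7 (limma log2 fold change -3.53 ± 0.22, adjusted p = 6.1e-06). Line 3205 had 34.8-fold less (limma, -5.12 ± 0.22, adjusted p = 8.9e-07). By limma H3f3b stood at log2 -1.19 ± 0.13 in line 264 (adjusted p = 0.00024) and -0.99 ± 0.13 in line 3205 (adjusted p = 0.00081). LPS raised H3f3b in every line: log2 1.05 ± 0.13 in RAW264.7, 1.15 ± 0.13 in line 264 and 0.70 ± 0.13 in line 3205 at 60 min. At 120 min the values were 1.22 ± 0.15, 1.41 ± 0.15 and 0.75 ± 0.15. In line 3205 H3f3b failed at both times without any 1 of the 4 libraries. H3f3a did not pass the threshold in any line at either time (0.03 ± 0.22, -0.09 ± 0.22 and -0.27 ± 0.22 at 60 min; 0.17 ± 0.26, -0.10 ± 0.26 and -0.62 ± 0.26 at 120 min).

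**Figure D1:**
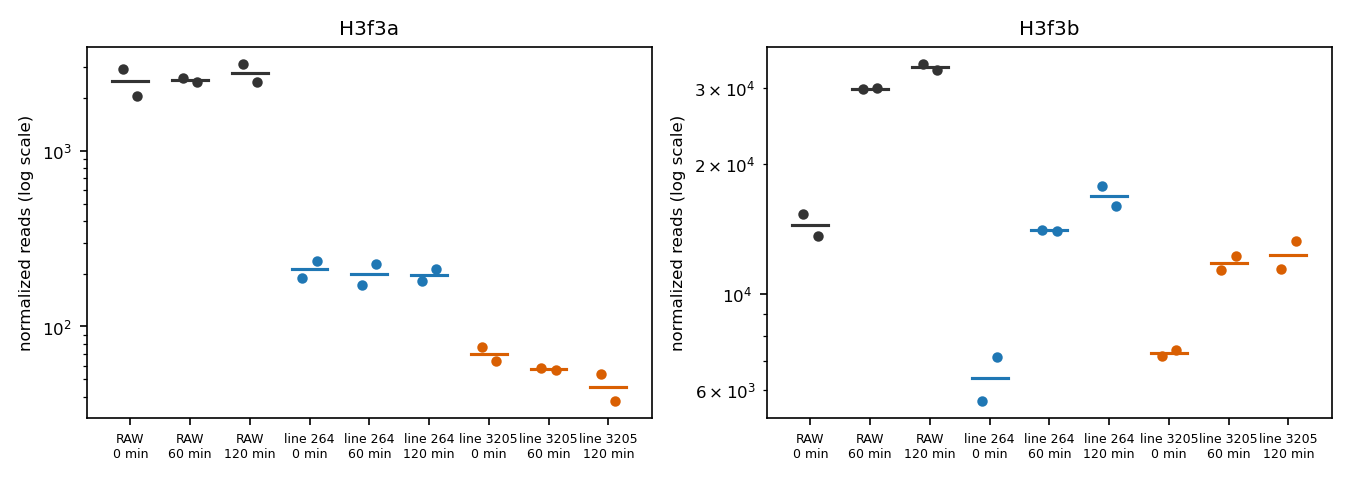
Normalized reads (log scale) of H3f3a and H3f3b in each of the 18 libraries by cell line and minutes of LPS; points are libraries and bars the mean of 2. The mean of H3f3a was 2491 in unstimulated RAW264.7, 212 in line 264 and 69.8 in line 3205.

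In primary macrophages the authors' deposited table lists 193 genes, of which 187 rose with LPS and 6 fell. The strongest induction in the authors' deposited table was of the neutrophil chemokine Cxcl2 (log2 fold change 11.39 ± 0.17). Next in the authors' deposited table came the cytokine genes Tnf (9.95 ± 0.09) and Il1b (9.91 ± 0.18) and the chemokine gene Cxcl1 (9.86 ± 0.18). The regulators of NF-kB signalling also rose in the authors' deposited table, with Nfkbiz at 8.77 ± 0.12 and Nfkbia, which encodes the inhibitor IkB alpha, at 7.07 ± 0.07. Tnfaip3, which encodes the feedback enzyme A20, stood at 6.03 in the authors' deposited table. The immediate early transcription factor genes Egr1 (7.53 ± 0.09) and Fos (3.62 ± 0.11) rose, and Ier5l (-2.30 ± 0.16) and the apoptosis gene Bbc3 (-1.39) fell, in the authors' deposited table. The same RNA values stand in a 60 and a 120 min table, which share 192 genes, so the stimulation time behind them could not be determined.

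Phosphorylated serine 31 of H3.3 (H3S31ph) rose over the induced genes at 60 min of LPS, with a median ratio of 3.89-fold over 187 genes. On the log2 scale the median was 1.96 (95% interval over genes 1.71 to 2.26), and 1.06 after division by the H3.3 ratio. The ratio was above 1 at 185 of the 187 genes. H3S31ph signal went from 1.69 to 50.3 at Cxcl2 (29.8-fold), 2.85 to 79.9 at Tnfaip3 (28.1-fold) and 2.32 to 57.6 at Nfkbia (24.8-fold). It went from 2.73 to 64.9 at Tnf (23.8-fold) and 1.79 to 40.2 at Il1a (22.4-fold). Among the smallest ratios at genes of sufficient signal were 1.51-fold at Bbc3 and 1.57-fold at the purine receptor gene P2ry13. Fixed lists ranked in the order NF-kB pathway and feedback genes (median 8.19-fold, 24 genes) and immediate early genes (5.84-fold, 20 genes). They were followed by inflammatory cytokines and chemokines (3.45-fold, 22 genes) and secondary response genes (2.01-fold, 6 genes). Each value comes from 1 library per time, so no test between replicates was possible.

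Phosphorylated serine 28 of H3 (H3S28ph) had a median ratio of 2.59-fold, above 1 at 186 of 187 genes. It was 6.77-fold at the TNF superfamily gene Tnfsf9, 6.16-fold at the chemokine gene Cxcl10 and 5.63-fold at the interferon gene Ifnb1. Total H3.3 had a median of 1.95-fold (185 of 187 genes above 1), with 1.15-fold at the MHC gene H2-Q7. The elongation mark H3K36me3 had a median of 1.61-fold (181 genes above 1), with 6.35-fold at the cytokine signalling inhibitor Socs3, 3.67-fold at Egr1 and 3.14-fold at Nfkbiz. The acetylation mark H3K27ac had a median of 1.18-fold with 136 genes above 1 and 51 below. It ran from 3.33-fold at the superoxide dismutase gene Sod2 down to 0.42-fold at Fos and 0.50-fold at Tnf. H3K36me2 had a median ratio of 1.0 (98 genes above 1, 89 below). Divided by the H3.3 ratio, the log2 medians became 0.46 for H3S28ph, and below 0 for H3K36me3 (from 0.69 to -0.20), H3K27ac (0.24 to -0.56) and H3K36me2 (-0.97). Across the 187 genes the ratio ranked with the authors' RNA fold change with a Spearman correlation of 0.40 for H3K36me3, 0.26 for H3S31ph and 0.26 for H3S28ph. It was 0.19 for H3K27ac, 0.02 for H3K36me2 and -0.06 for H3.3. Genes are not independent replicates, and no p-value was attached to these 6 relations.

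**Figure D2:**
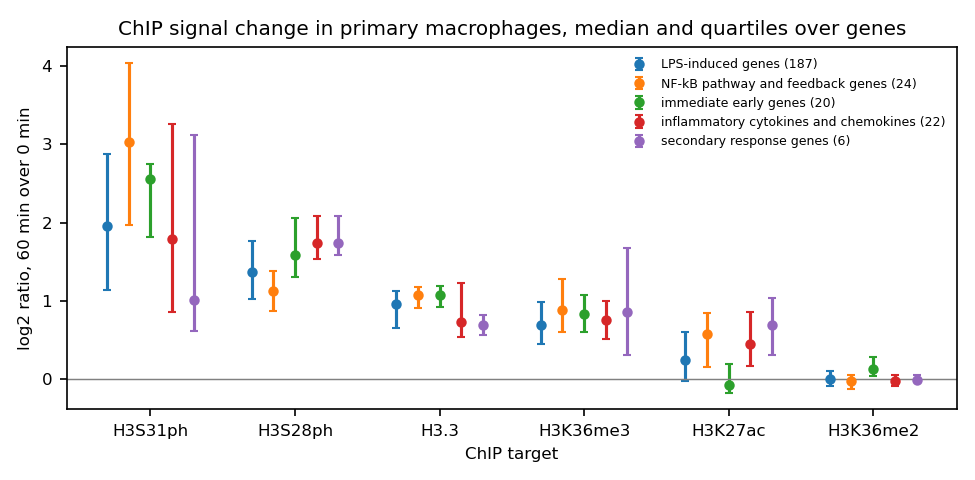
Log2 ratio of ChIP signal at 60 min over 0 min of LPS in primary macrophages for 6 targets and 5 gene groups; points are medians over genes and bars run from the lower to the upper quartile. H3S31ph had the highest median in 4 of the 5 groups, from 1.79 over cytokines and chemokines to 3.03 over NF-kB genes; over secondary response genes it was 1.01, against 1.74 for H3S28ph.

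In RAW264.7 cells at 60 min the interferon gene Ifnb1 rose 309-fold (log2 8.27 ± 1.0) and the inflammasome cytokine gene Il1b 209-fold (log2 7.71 ± 1.13). Cxcl2 rose 208-fold (log2 7.70 ± 0.44) and the nuclear IkB gene Nfkbiz 192-fold (log2 7.58 ± 0.21). By limma the adjusted p was 0.0016, 0.0052, 1e-05 and 8.3e-08. The 4 largest decreases were of Txnip, an inhibitor of thioredoxin and glucose uptake (8.18-fold (log2 -3.03 ± 0.22)), the zinc finger gene Zfp763 (-2.76 ± 0.31), the MAP kinase phosphatase gene Dusp7 (-2.55 ± 0.22) and the Polycomb gene Cbx2 (-2.47 ± 0.36). Inflammatory genes of the fixed panel rose: Tnf 5.34 ± 0.38, Cxcl10 6.21 ± 0.52 and Ccl4 5.18 ± 0.49. So did the regulators Tnfaip3 5.50 ± 0.19, Egr1 4.66 ± 0.27 and Nfkbia 2.32 ± 0.13. The cytokine gene Il6 had no read at 0 min and was at least 14.5-fold higher at 60 min. Not passing were Fos 0.86 ± 0.44 and Nos2 1.05 ± 1.56. Setd2, a methyltransferase of H3K36 (0.14 ± 0.10), Zmynd11, a reader of H3.3 (0.11 ± 0.12), and Chuk, the kinase IKK alpha (0.30 ± 0.10), did not pass. Immediate early genes rose as a group, 25 of 31 (26 adjusted over the list alone). Among them were the phosphatase genes Dusp1 (5.53 ± 0.21) and Dusp2 (5.50 ± 0.20), the AP-1 gene Junb (4.04 ± 0.18) and the mRNA decay gene Zfp36 (4.58 ± 0.21). Inflammatory cytokines and chemokines rose at 18 of 28 genes (26 adjusted over the list alone). NF-kB pathway and feedback genes rose at 23 of 33 (26), including the apoptosis inhibitor Cflar (2.82 ± 0.14). Secondary response genes rose at 8 of 18 (11), including Irg1 (5.81 ± 0.39), which encodes the itaconate enzyme. Camera adjusted p with an estimated correlation was 0.00079, 0.00066, 0.00011 and 0.04 for these lists (0.0512 for the last with a replicate block too). Interferon-stimulated genes rose at 4 of 34 (7 adjusted over the list alone; adjusted p = 0.56 with an estimated correlation), including Oasl1 (3.21 ± 0.34) and Rsad2 (2.89 ± 0.39). Stress genes of the unfolded protein list rose at 4 of 23, with Atf3 at 3.24 ± 0.30 and Ppp1r15a at 5.01 ± 0.13 (adjusted p = 0.29 with an estimated correlation). The p53 targets rose at 5 of 23 with Btg2 at 4.98 ± 0.53 and Mdm2 at 1.83 ± 0.23 (0.14). Genes of cholesterol synthesis rose at 3 of 23 with Hmgcs1 at 1.48 ± 0.19 and Insig1 at 2.06 ± 0.34 (0.54). The myeloid factor gene Cebpa fell (-1.06 ± 0.19). Insig1 (adjusted p 0.058 to 0.11) and Cebpa (0.066 to 0.16) failed without any 1 of the 4 libraries. Il1b and Cbx2 failed without RAW 0 min replicate 2 or RAW 60 min replicate 2. In all, 287 genes rose and 228 fell (640 and 758 with a replicate block; 179 to 247 in all without 1 library).

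At 120 min RAW264.7 cells had raised the cytokine gene Lif 4560-fold (log2 12.16 ± 0.94), Il1b 2750-fold (log2 11.43 ± 1.32) and Il1a 1780-fold (log2 10.80 ± 0.69). Il6 was at least 762-fold higher. Their limma adjusted p was 6.2e-05, 0.00061, 2.1e-05 and 7.8e-05. The 4 largest decreases were of the corepressor gene Cbfa2t3 (51.1-fold (log2 -5.67 ± 0.83)), the sphingosine receptor gene S1pr1 (-4.90 ± 0.41), the ubiquitin ligase gene Rnf144b (-4.38 ± 0.53) and Kbtbd11 (-3.90 ± 0.49). Panel genes that rose were Ifnb1 9.81 ± 1.15, Cxcl2 8.02 ± 0.42, Cxcl10 7.80 ± 0.67, Ccl4 6.90 ± 0.62 and Tnf 6.32 ± 0.40. The regulators Tnfaip3 5.30 ± 0.20, Nfkbia 3.16 ± 0.13 and Egr1 1.78 ± 0.31 also rose. The nitric oxide synthase gene Nos2 stood at 4.02 ± 1.49 (limma adjusted p = 0.13, and 0.00064 with the replicate block). Fos -1.29 ± 0.43, Setd2 -0.23 ± 0.12, Zmynd11 0.05 ± 0.11 and Chuk 0.39 ± 0.11 did not pass. Chuk (0.011) and Fos (0.036) passed with the replicate block. Cytokines and chemokines rose at 28 of 29 genes (29 adjusted over the list alone), NF-kB genes at 28 of 33 (30) and immediate early genes at 22 of 31 (24), including Dusp1 (5.84 ± 0.21). Secondary response genes rose at 18 of 20 (19), including Irg1 (7.56 ± 0.47) and Socs3 (5.21 ± 0.34). For these 4 lists camera adjusted p with an estimated correlation was 0.0098, 0.0035, 0.0044 and 0.016. Interferon-stimulated genes rose at 14 of 35 (22 adjusted over the list alone; adjusted p = 0.50 with an estimated correlation), with the RNA sensor gene Ifih1 at 4.18 ± 0.60 and Oasl1 at 4.31 ± 0.49. The costimulatory gene Cd80 (2.13 ± 0.26) and the death receptor gene Fas (4.38 ± 0.48) rose, and the inhibitory receptor gene Sirpa fell (-1.21 ± 0.17). Cell cycle genes fell at 3 of 32 (7 adjusted over the list alone; adjusted p = 0.64 with an estimated correlation), including the kinetochore gene Cenpf (-0.99 ± 0.19) and the cyclin gene Ccne1 (-1.09 ± 0.26). Egr1, Cenpf and Ccne1 failed without RAW 0 min replicate 1 or RAW 120 min replicate 1. Cenpf and Ccne1 also failed without RAW 0 min replicate 2. In all, 886 genes rose and 963 fell (1974 and 2163 with a replicate block; 671 to 981 in all without 1 library).

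Line 264 at 60 min raised Cxcl2 285-fold (log2 8.15 ± 0.44) and the granulocyte growth factor gene Csf3 111-fold (log2 6.80 ± 0.78). It raised Cxcl10 91.7-fold (log2 6.52 ± 0.52) and Nfkbiz 84.9-fold (log2 6.41 ± 0.21). The adjusted p of limma was 8.2e-06, 0.0017, 0.00017 and 4.2e-07. The 4 largest decreases were of the zinc finger genes Zfp763 (6.07-fold (log2 -2.60 ± 0.31)), Zfp85 (-2.41 ± 0.47) and Zfp60 (-2.30 ± 0.25) and the nuclear RNA Neat1 (-2.41 ± 0.23). Panel genes that rose were Tnf 5.56 ± 0.38, Ccl4 3.24 ± 0.49, Egr1 5.22 ± 0.27 and Fos 4.59 ± 0.44. The NF-kB inhibitors Tnfaip3 5.06 ± 0.19 and Nfkbia 2.76 ± 0.13 also rose. Il1b (5.05 ± 1.13) and Ifnb1 (4.46 ± 1.0) each had an adjusted p of 0.083, and 0.00067 and 0.012 with the replicate block. Il6 had 1 read in the 0 min libraries and 1 in the 60 min libraries. Nos2 -0.24 ± 1.56, Setd2 -0.06 ± 0.10, Zmynd11 0.08 ± 0.12 and Chuk 0.26 ± 0.10 did not pass. Immediate early genes rose at 21 of 31 (26 adjusted over the list alone), cytokines and chemokines at 11 of 28 (17), NF-kB genes at 18 of 33 (24) and secondary response genes at 4 of 18 (7). Adjusted p with an estimated correlation was 0.00052, 0.00086, 7.5e-05 and 0.084. Zfp85 (adjusted p 0.065 to 0.34) failed without any 1 of the 4 libraries. Ccl4 (0.079 and 0.096) failed without line 264 0 min replicate 2 or line 264 60 min replicate 1. Ifnb1 (adjusted p 0.0023) passed without line 264 60 min replicate 2. In all, 142 genes rose and 64 fell (364 and 327 with a replicate block; 109 to 151 in all without 1 library).

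Line 3205 at 60 min raised Cxcl2 515-fold (log2 9.01 ± 0.44), Tnf 127-fold (log2 6.99 ± 0.38) and the AP-1 gene Fosb 126-fold (log2 6.98 ± 0.80). Adjusted p by limma was 4.1e-06, 7.2e-06 and 0.0015. Csf3, with 2 reads at 0 min, was 483-fold higher (counting interval 133 to 3991). The 4 largest decreases were of Neat1 (4.37-fold (log2 -2.13 ± 0.23)), Zfp60 (-1.96 ± 0.25), Zfp759 (-1.95 ± 0.36) and Zfp157 (-1.90 ± 0.27). Panel genes that rose were Il1b 6.30 ± 1.13, Cxcl10 6.26 ± 0.52, Ifnb1 5.27 ± 1.0 and Ccl4 3.09 ± 0.49. So did Egr1 5.50 ± 0.27, Tnfaip3 5.50 ± 0.19, Fos 4.24 ± 0.44 and Nfkbia 3.55 ± 0.13. Il6 had 0 and 2 reads at the 2 times. Nos2 1.17 ± 1.56, Setd2 0.00 ± 0.10, Zmynd11 0.03 ± 0.12 and Chuk 0.21 ± 0.10 did not pass. Egr1 reached a mean of 227 normalized reads from 3.93, against 49761 from 2000 in RAW264.7 and 29797 from 807 in line 264. Immediate early genes rose at 23 of 31 (28 adjusted over the list alone), cytokines and chemokines at 11 of 28 (19), NF-kB genes at 20 of 33 (27) and secondary response genes at 6 of 18 (6). For them adjusted p with an estimated correlation was 0.00032, 0.00084, 5.4e-05 and 0.11. Ifnb1 (adjusted p 0.11 to 0.28) and Zfp759 (0.074 to 0.27) failed without any 1 of the 4 libraries. Il1b (0.12 and 0.24) failed without line 3205 0 min replicate 2 or line 3205 60 min replicate 1. Ccl4 and Zfp157 failed without line 3205 0 min replicate 1 or line 3205 60 min replicate 2. In all, 164 genes rose and 48 fell (403 and 288 with a replicate block; 104 to 167 in all without 1 library).

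By 120 min line 264 had raised Csf3 1800-fold (log2 10.81 ± 0.63), Lif 1300-fold (log2 10.35 ± 0.94), Cxcl10 454-fold (log2 8.83 ± 0.67) and Cxcl2 421-fold (log2 8.72 ± 0.42). By limma the adjusted p was 1.8e-05, 0.00023, 8.1e-05 and 5.7e-06. The 4 largest decreases were of the atrophy-related ligase gene Fbxo32 (10.1-fold (log2 -3.33 ± 0.60)), the PI3 kinase inhibitor gene Pik3ip1 (-3.24 ± 0.63), Kbtbd11 (-3.23 ± 0.49) and Rnf144b (-2.89 ± 0.53). Panel genes that rose were Il1b 7.90 ± 1.32, Ifnb1 6.77 ± 1.15, Ccl4 5.35 ± 0.62 and Tnf 5.02 ± 0.40. So did Tnfaip3 4.35 ± 0.20, Egr1 2.97 ± 0.31, Nfkbia 2.95 ± 0.13 and Chuk 0.48 ± 0.11. Il6 went from 1 read to 185 reads over 2 libraries, 231-fold higher (counting interval 41 to 9175). Nos2 4.27 ± 1.49 did not pass. Nor did Fos 1.49 ± 0.43, Setd2 -0.26 ± 0.12 and Zmynd11 -0.08 ± 0.11. Fos (0.026) and Nos2 (0.00073) passed with the replicate block. Cytokines and chemokines rose at 24 of 29 (28 adjusted over the list alone), NF-kB genes at 27 of 33 (29), immediate early genes at 20 of 31 (24) and secondary response genes at 14 of 20 (15). Their adjusted p was 0.0096, 0.0018, 0.0018 and 0.022 with an estimated correlation. Interferon-stimulated genes rose at 6 of 35 (8 adjusted over the list alone, adjusted p = 0.66 with an estimated correlation). Chuk (adjusted p 0.13 to 0.17) failed without any 1 of the 4 libraries. Il1b (0.055) and Rnf144b (0.07) failed without line 264 0 min replicate 2. Il1b (0.066), Fbxo32 (0.075), Pik3ip1 (0.079) and Rnf144b (0.1) failed without line 264 120 min replicate 1. Ifnb1 (0.057), Fbxo32 (0.11), Pik3ip1 (0.15), Kbtbd11 (0.051) and Rnf144b (0.074) failed without line 264 0 min replicate 1. Fbxo32 (0.055) and Pik3ip1 (0.091) failed without line 264 120 min replicate 2. In all, 503 genes rose and 445 fell (1356 and 1503 with a replicate block; 348 to 586 in all without 1 library).

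Line 3205 at 120 min raised Cxcl2 1140-fold (log2 10.15 ± 0.42), Ifnb1 524-fold (log2 9.03 ± 1.15) and Cxcl10 290-fold (log2 8.18 ± 0.67). Adjusted p by limma was 1.8e-06, 0.0018 and 1e-04. Csf3 was 6209-fold higher (counting interval 1718 to 51270). The 4 largest decreases were of the RAB GTPase regulator Tbc1d30 (13.1-fold (log2 -3.71 ± 0.74)), Kbtbd11 (-3.58 ± 0.49), Fbxo32 (-3.46 ± 0.60) and Cbfa2t3 (-3.43 ± 0.83). Panel genes that rose were Il1b 8.12 ± 1.32, Tnf 7.02 ± 0.40, Ccl4 5.93 ± 0.62, Tnfaip3 4.57 ± 0.20, Nfkbia 3.64 ± 0.13 and Egr1 2.74 ± 0.31. Il6, with no read at 0 min, was at least 13-fold higher. Nos2 5.78 ± 1.49 did not pass. Nor did Fos 0.81 ± 0.43, Setd2 -0.28 ± 0.12, Zmynd11 0.08 ± 0.11 and Chuk 0.43 ± 0.11. Chuk (0.01) and Nos2 (0.00012) passed with the replicate block. Cytokines and chemokines rose at 22 of 29 (29 adjusted over the list alone), NF-kB genes at 24 of 33 (28), immediate early genes at 23 of 31 (25) and secondary response genes at 15 of 20 (17). Their adjusted p was 0.0073, 0.0014, 0.0014 and 0.022 with an estimated correlation. Cbfa2t3 (adjusted p 0.089 to 0.25) failed without any 1 of the 4 libraries. Il1b (0.063), Il6 (0.15), Tbc1d30 (0.1) and Fbxo32 (0.078) failed without line 3205 120 min replicate 1. Il6 (0.11), Tbc1d30 (0.16) and Fbxo32 (0.083) failed without line 3205 0 min replicate 1. Il6 (0.07) failed without line 3205 0 min replicate 2. Tbc1d30 (0.095) and Fbxo32 (0.05) failed without line 3205 120 min replicate 2. Nos2 (adjusted p 0.036) passed without line 3205 0 min replicate 1. Chuk (0.047) passed without line 3205 0 min replicate 2. In all, 505 genes rose and 373 fell (1253 and 1243 with a replicate block; 323 to 683 in all without 1 library).

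Before LPS, line 264 lacked transcripts that were abundant in RAW264.7: the scavenger receptor gene Cd36 was at least 13439-fold lower and the lysozyme gene Lyz1 4250-fold (log2 -12.05 ± 0.46) lower. The protocadherin gene Pcdh7 was 12690-fold lower (counting interval 2277 to 501288) and the zinc finger gene Zfhx4 5172-fold lower (counting interval 1431 to 42712). Their limma adjusted p was 1.5e-06, 3.2e-07, 4.3e-07 and 6.8e-07. The 4 largest increases began with the transporter gene Svopl, 4437-fold higher (counting interval 796 to 175281), and the myosin kinase gene Mylk, 1512-fold higher (counting interval 418 to 12491). They were followed by the sodium channel gene Scn11a, 739-fold (log2 9.53 ± 0.37), and the hyaluronan-binding gene Itih5, 717-fold (log2 9.49 ± 0.59). Panel genes lower in line 264 besides the H3.3 pair were Fos -4.02 ± 0.44, Cxcl10 -2.02 ± 0.52 and Egr1 -1.30 ± 0.27, and Chuk was higher (0.44 ± 0.10). Cxcl2 -1.13 ± 0.44, Ccl4 -1.24 ± 0.49 and Tnf -0.23 ± 0.38 did not pass. Nor did Ifnb1 0.94 ± 1.0, Il1b 0.48 ± 1.13 and Nos2 0.58 ± 1.56. Nor did Tnfaip3 -0.61 ± 0.19, Nfkbia -0.29 ± 0.13, Setd2 -0.02 ± 0.10 and Zmynd11 0.11 ± 0.12. Il6 was at or under 1 read in both. Tnfaip3 (0.035) passed with the replicate block. Macrophage identity genes were lower at 15 of 25 and higher at 3 (17 and 3 adjusted over the list alone; adjusted p = 0.014 with an estimated correlation). Among them were the scavenger receptor gene Msr1 (-8.19 ± 0.83) and the transcription factor gene Cebpa (-1.65 ± 0.19). Lysosome and phagocytosis genes were lower at 11 of 24 and higher at 1 (12 and 2 adjusted over the list alone; 0.024 with an estimated correlation and 0.0678 with a replicate block too). They include the cathepsins Ctss (-1.12 ± 0.17) and Ctsl (-1.13 ± 0.19) and the granulin gene Grn (-0.83 ± 0.13). The early genes Plk2 -7.69 ± 0.87, Klf4 -6.75 ± 0.80 and Myc -4.24 ± 0.67 differed, as did the osteoclast genes Itgb3 6.05 ± 0.76, Ctsk -4.97 ± 0.88 and Mmp9 1.80 ± 0.32. So did the p53 targets Tnfrsf10b -3.67 ± 0.42 and Pmaip1 -2.48 ± 0.17. Cytokine and costimulatory genes that differed were Cd80 1.67 ± 0.23, Ccl5 2.37 ± 0.39, Ccl9 -2.12 ± 0.23 and Csf2 2.98 ± 0.63. Cxcl10 (adjusted p 0.09 to 0.17), Chuk (0.072 to 0.11) and Csf2 (0.052 to 0.079) failed without any 1 of the 4 libraries. Egr1 (0.099 and 0.081) failed without RAW 0 min replicate 2 or line 264 0 min replicate 1. Cxcl2 (adjusted p 0.024) passed without line 264 0 min replicate 2. Tnfaip3 (0.039) passed without line 264 0 min replicate 1. In all, 1317 genes were higher and 963 lower (2201 and 1836 with a replicate block; 1199 to 1705 in all without 1 library).

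Unstimulated line 3205 also lacked Cd36 (6630-fold (log2 -12.70 ± 0.71) lower), Pcdh7 (10919-fold lower (counting interval 1959 to 431330)) and Lyz1 (2270-fold (log2 -11.15 ± 0.46) lower). The zinc transporter gene Slc30a4 was at least 987-fold lower. The adjusted p of limma was 3.5e-06, 8.1e-07, 8.1e-07 and 3e-04. The 4 largest increases began with the glutamate transporter gene Slc1a3, 10824-fold higher (counting interval 1942 to 427547), and the nucleotide receptor gene P2ry14, at least 766-fold higher. They were followed by Mylk, 2096-fold higher (counting interval 580.0 to 17310), and the homeobox gene Rhox2g, at least 443-fold higher. Egr1 was lower (-8.64 ± 0.27), with a mean of 3.93 normalized reads against 2000. It was also lower at 60 and 120 min (-7.80 ± 0.27 and -7.68 ± 0.31). Panel genes lower before LPS were Cxcl2 -2.52 ± 0.44, Fos -2.52 ± 0.44, Ccl4 -2.33 ± 0.49, Tnf -2.30 ± 0.38, Nfkbia -1.17 ± 0.13 and Tnfaip3 -0.83 ± 0.19. Cxcl10 -1.75 ± 0.52, Il1b 1.35 ± 1.13, Ifnb1 0.17 ± 1.0 and Nos2 1.04 ± 1.56 did not pass. Nor did Chuk -0.28 ± 0.10, Setd2 -0.02 ± 0.10 and Zmynd11 0.24 ± 0.12. Chuk (0.034) and Cxcl10 (0.023) passed with the replicate block, and Il6 had no read in either. NF-kB pathway and feedback genes were lower at 11 of 33 and higher at none (17 adjusted over the list alone; adjusted p = 0.02 with an estimated correlation and 0.0622 with a replicate block too). They include the subunit genes Relb (-1.37 ± 0.16) and Nfkb2 (-1.19 ± 0.16) and the nuclear cofactor Bcl3 (-2.10 ± 0.25). Immediate early genes were lower at 10 of 31 and higher at 2 (11 and 2 adjusted over the list alone; 0.29 with an estimated correlation). Junb (-2.12 ± 0.18), Dusp1 (2.0 ± 0.21) and Klf4 (-5.65 ± 0.80) differed. Integrated stress genes were lower at 7 of 23 (8 adjusted over the list alone; 0.34 with an estimated correlation), with Trib3 -1.85 ± 0.20, Asns -1.24 ± 0.14 and Chac1 -1.51 ± 0.28. Targets of p53 were lower at 8 of 23 (10; 0.34), with Fas at -3.54 ± 0.49 and Phlda3 286-fold lower (counting interval 50.9 to 11332). Macrophage identity genes split 7 higher and 6 lower (9 and 9 adjusted over the list alone). Among them and the costimulatory genes were C1qb 6.70 ± 0.75, Fcgr1 1.14 ± 0.17, Msr1 -6.08 ± 0.83, Cd86 4.62 ± 0.62 and Cd80 2.51 ± 0.23. Also Ptgs2 2.74 ± 0.34, Ccl5 2.27 ± 0.39, Prtn3 4.15 ± 0.60 and Mmp9 3.07 ± 0.32 differed, and the osteoclast protease gene Ctsk was 72.6-fold lower (counting interval 24.5 to 355). Genes of MHC class II presentation were higher at 6 of 12 and lower at 1 (6 and 2 adjusted over the list alone; 0.40 with an estimated correlation). Tnfaip3 (adjusted p 0.14 and 0.07) failed without RAW 0 min replicate 2 or line 3205 0 min replicate 2. Tnfaip3 (0.056) and Ccl4 (0.064) failed without line 3205 0 min replicate 1. Ccl4 (0.096) and Chac1 (0.063) failed without RAW 0 min replicate 1. Cxcl10 (adjusted p 0.038) and Chuk (0.043) passed without line 3205 0 min replicate 2. In all, 1457 genes were higher and 1019 lower (2486 and 2095 with a replicate block; 1226 to 2348 in all without 1 library).

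Of the genes called before LPS, 717 were higher in both lines, 427 were lower in both and 50 went opposite ways. Independent lists would share 110.9 and 56.7, a value that leaves out the shared RAW264.7 libraries, so part of the excess may come from these. The log2 fold changes of both lines correlated at r = 0.65 across 17301 genes, and 68.8% had the same sign. Noise simulated without true differences, with the RAW264.7 libraries shared, gave 0.50 and 66.7%, whatever the size of the noise. The covariance shows that size: 0.988 in the data and 0.123 in the simulations. In a test added after seeing the data, each line had its own RAW264.7 library (same replicate number), so the simulated values do not apply. The 2 ways gave r = 0.52 and 0.48 before LPS (same sign 59.6% and 56.8%), so sharing does not explain all of r.

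At 60 min of LPS, line 264 remained far below RAW264.7 for Cd36, 18103-fold lower (counting interval 6194 to 87790), and Lyz1, 3220-fold (log2 -11.65 ± 0.46) lower. So were Pcdh7, 6376-fold lower (counting interval 2181 to 30923), and the stress kinase gene Plk2, 1910-fold (log2 -10.90 ± 0.87) lower. Their limma adjusted p was 2.2e-06, 4.1e-07, 5.2e-07 and 2.8e-05. The 4 largest increases began with Itih5 (at least 887-fold higher) and Mylk (at least 564-fold higher). Next came Svopl, 712-fold higher (counting interval 243 to 3453), and the actin filament gene Afap1, 308-fold higher (counting interval 105 to 1494). H3f3a (-3.66 ± 0.22), H3f3b (-1.09 ± 0.13), Ccl4 (-3.17 ± 0.49) and Tnfaip3 (-1.05 ± 0.19) were lower, and Chuk was higher (0.41 ± 0.10). Il6 was 68.8-fold lower (counting interval 11.3 to 2820). Ifnb1 -2.87 ± 1.0, Il1b -2.18 ± 1.13 and Cxcl10 -1.71 ± 0.52 did not pass. Nor did Cxcl2 -0.67 ± 0.44, Tnf -0.01 ± 0.38 and Nos2 -0.72 ± 1.56. Nor did Egr1 -0.74 ± 0.27, Fos -0.30 ± 0.44 and Nfkbia 0.16 ± 0.13. Nor did Setd2 -0.22 ± 0.10 and Zmynd11 0.08 ± 0.12. Cxcl10 (0.025), Ifnb1 (0.023) and Il1b (0.017) passed with the replicate block. Cytokines and chemokines were lower at 7 of 28 genes and higher at 2 (12 and 2 adjusted over the list alone; adjusted p = 0.13 with an estimated correlation). Macrophage identity genes were lower at 13 of 25 (14; 0.028, and 0.071 with a replicate block too). Chuk (adjusted p 0.073 to 0.16) failed without any 1 of the 4 libraries. Tnfaip3 (0.051) failed without line 264 60 min replicate 1. Cxcl10 (adjusted p 0.0028) and Ifnb1 (0.0026) passed without line 264 60 min replicate 1. In all, 1463 genes were higher and 1177 lower (2475 and 2173 with a replicate block; 1487 to 1571 in all without 1 library).

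Line 3205 at 60 min was below RAW264.7 for Cd36, 1530-fold (log2 -10.58 ± 0.71), and Lyz1, 1520-fold (log2 -10.57 ± 0.46). It was also below for Slc30a4, 6325-fold lower (counting interval 1134 to 249934), and the endothelial lipase gene Lipg, at least 1101-fold lower. By limma the adjusted p was 1.1e-05, 9.3e-07, 0.00033 and 3.1e-06. The 4 largest increases were of Mylk (at least 712-fold higher) and Slc1a3, 1429-fold higher (counting interval 489 to 6930). Next were the small heat shock gene Hspb8 (at least 519-fold higher) and P2ry14 (at least 293-fold higher). H3f3a (-5.43 ± 0.22), H3f3b (-1.34 ± 0.13), Ccl4 (-4.41 ± 0.49), Tnfaip3 (-0.83 ± 0.19) and Chuk (-0.37 ± 0.10) were lower, and Il6 was 41.7-fold lower (counting interval 10.4 to 363). Ifnb1 -2.83 ± 1.0, Cxcl10 -1.69 ± 0.52 and Cxcl2 -1.22 ± 0.44 did not pass. Nor did Tnf -0.65 ± 0.38, Il1b -0.06 ± 1.13 and Nos2 1.15 ± 1.56. Nor did Fos 0.87 ± 0.44, Nfkbia 0.06 ± 0.13, Setd2 -0.16 ± 0.10 and Zmynd11 0.16 ± 0.12. Cxcl10 (0.026), Ifnb1 (0.024) and Tnf (0.046) passed with the replicate block. NF-kB pathway and feedback genes were lower at 18 of 33 genes and higher at none (19 adjusted over the list alone; adjusted p = 0.013 with an estimated correlation). Cytokines and chemokines were lower at 6 of 28 (11; 0.18). Chuk (adjusted p 0.099 to 0.21) failed without any 1 of the 4 libraries. Tnfaip3 (0.1, 0.071 and 0.13) failed without RAW 60 min replicate 1 or 2 or line 3205 60 min replicate 1. In all, 1548 genes were higher and 1118 lower (2687 and 2146 with a replicate block; 1407 to 1562 in all without 1 library).

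At 120 min line 264 was below RAW264.7 for Cd36 (at least 14012-fold lower), Pcdh7 (at least 11419-fold lower) and Lyz1, 4190-fold (log2 -12.03 ± 0.48). It was also below for the adhesion gene Flrt2, 6141-fold lower (counting interval 1102 to 242613). The adjusted p of limma was 7.1e-06, 2.8e-07, 5.2e-07 and 6.5e-06. The 4 largest increases were of Itih5, 3376-fold higher (counting interval 606 to 133392), and Scn11a, 1240-fold higher (counting interval 424 to 6015). Next came Svopl, 1510-fold higher (counting interval 418 to 12475), and Afap1 (at least 384-fold higher). Panel genes that were lower were Il6 at -4.02 ± 0.83, Ccl4 -2.78 ± 0.62, Tnfaip3 -1.56 ± 0.20, Tnf -1.53 ± 0.40 and Nfkbia -0.50 ± 0.13. Also lower were H3f3a (-3.80 ± 0.26) and H3f3b (-1.0 ± 0.15), and Chuk was higher (0.53 ± 0.11). Il1b -3.05 ± 1.32, Ifnb1 -2.10 ± 1.15, Cxcl10 -1.0 ± 0.67, Cxcl2 -0.43 ± 0.42 and Nos2 0.83 ± 1.49 did not pass. Nor did Fos -1.25 ± 0.43, Egr1 -0.11 ± 0.31, Setd2 -0.05 ± 0.12 and Zmynd11 -0.02 ± 0.11. Fos (0.038) and Il1b (0.0012) passed with the replicate block. The anti-inflammatory cytokine genes Il10 (-6.07 ± 0.55) and Il1rn (-4.51 ± 0.35) were lower. Ccl9 -2.91 ± 0.30, Csf2 3.68 ± 0.64, Lcn2 4.38 ± 0.82 and Serpinb2 -6.19 ± 1.0 differed. Also lower were the interferon-responsive genes Mx1 (-2.92 ± 0.76) and Cxcl9 (at least 16.3-fold lower). Interferon-stimulated genes were lower at 6 of 35 and higher at none (7 adjusted over the list alone; 22 lower with the replicate block; adjusted p = 0.71 with an estimated correlation). Cytokines and chemokines were lower at 9 of 29 (9; 0.47). Nfkbia (adjusted p 0.12 to 0.16) failed without any 1 of the 4 libraries. Il6 (0.1), Ccl4 (0.13), Tnf (0.18), Chuk (0.1) and Mx1 (0.22) failed without RAW 120 min replicate 1. Il6 (0.082), Ccl4 (0.1), Tnf (0.22), Chuk (0.079) and Mx1 (0.19) failed without line 264 120 min replicate 2. Tnf (0.1), Mx1 (0.061) and Lcn2 (0.052) failed without RAW 120 min replicate 2. Chuk (0.057) failed without line 264 120 min replicate 1. Cxcl10 (adjusted p 0.025) and Ifnb1 (0.0051) passed without line 264 120 min replicate 1. Fos (0.04) passed without RAW 120 min replicate 2. In all, 1279 genes were higher and 1069 lower (2351 and 2064 with a replicate block; 1169 to 1561 in all without 1 library).

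Line 3205 at 120 min was below RAW264.7 for Pcdh7, 56358-fold lower (counting interval 10114 to 2226084), and Cd36, 4030-fold (log2 -11.98 ± 0.91). It was also below for Lyz1, 2940-fold (log2 -11.52 ± 0.48), and the membrane protein gene Tmem26, 9650-fold lower (counting interval 1731 to 381238). Their limma adjusted p was 8.3e-07, 2.9e-05, 8.5e-07 and 1.8e-05. The 4 largest increases were of Hspb8 (at least 996-fold higher), and Slc1a3, 2287-fold higher (counting interval 410.0 to 90371). Next came Klhl30, 2046-fold higher (counting interval 367 to 80846), and Mylk, 1454-fold higher (counting interval 402 to 12010). Il6 was lower (-6.02 ± 0.83). Also Ccl4 -3.29 ± 0.62, Tnf -1.6 ± 0.40, Tnfaip3 -1.57 ± 0.20, Nfkbia -0.70 ± 0.13, H3f3a -5.91 ± 0.26 and H3f3b -1.45 ± 0.15 were lower. Il1b -1.96 ± 1.32, Cxcl10 -1.37 ± 0.67, Ifnb1 -0.61 ± 1.15, Cxcl2 -0.39 ± 0.42 and Nos2 2.79 ± 1.49 did not pass. Nor did Fos -0.42 ± 0.43, Chuk -0.23 ± 0.11, Setd2 -0.07 ± 0.12 and Zmynd11 0.26 ± 0.11. Il1b (0.013) and Nos2 (0.0044) passed with the replicate block. NF-kB genes were lower at 14 of 33 and higher at none (17 adjusted over the list alone; adjusted p = 0.15 with an estimated correlation), with the paracaspase gene Malt1 at -2.80 ± 0.27. Interferon-stimulated genes were lower at 8 of 35 (11; 0.54), with Ifih1 at -3.45 ± 0.60 and Cxcl9 39.7-fold lower (counting interval 10.3 to 339). The prostaglandin enzyme gene Ptgs2 was higher (1.74 ± 0.41), as were the granule protease genes Prtn3, 48.9-fold higher (counting interval 16.6 to 238), and Elane (at least 3.39-fold higher). Tnf (adjusted p 0.082 to 0.16) and Elane (0.09 to 0.2) failed without any 1 of the 4 libraries. Ccl4 (0.069) and Nfkbia (0.055) failed without RAW 120 min replicate 1. Nfkbia (0.064) and Cxcl9 (0.051) failed without line 3205 120 min replicate 2. Ptgs2 (0.14 and 0.12) failed without RAW 120 min replicate 2 or line 3205 120 min replicate 1. In all, 1385 genes were higher and 1045 lower (2563 and 2190 with a replicate block; 1109 to 1602 in all without 1 library).

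Tested as a difference between responses, the circadian repressor gene Bhlhe40 had a different response to LPS at 60 min in both lines. The limma difference was -2.10 ± 0.23 in line 264 (adjusted p = 0.035) and -2.46 ± 0.23 in line 3205 (adjusted p = 0.016). Its mean went from 693 to 1830 normalized reads in RAW264.7, from 1932 to 1203 in line 264 and from 1305 to 624 in line 3205. The RAS exchange factor gene Rasgef1b rose from 1183 to 17990 in RAW264.7 and stood at 5848 and 8764 in line 264 (limma difference -3.33 ± 0.38, adjusted p = 0.035). Txnip went from 13342 to 1613 in RAW264.7 and from 17574 to 13830 in line 264 (limma, 2.68 ± 0.31, adjusted p = 0.035). In line 3205, without calls, Rasgef1b went from 7240 to 13259 and Txnip from 19519 to 7446. No gene of the fixed panel passed in line 264. Ifnb1 -3.81 ± 1.41, Il1b -2.66 ± 1.6 and Ccl4 -1.93 ± 0.69 did not pass. Nor did Nos2 -1.29 ± 2.21, Cxcl2 0.45 ± 0.62, Cxcl10 0.31 ± 0.74 and Tnf 0.22 ± 0.53. Nor did Fos 3.73 ± 0.63, Egr1 0.56 ± 0.38, Nfkbia 0.45 ± 0.18 and Tnfaip3 -0.44 ± 0.28. Nor did Setd2 -0.20 ± 0.14, H3f3a -0.13 ± 0.32, H3f3b 0.10 ± 0.18, Zmynd11 -0.03 ± 0.18 and Chuk -0.03 ± 0.15. In line 3205 none passed. Ifnb1 -3.0 ± 1.41, Ccl4 -2.09 ± 0.69 and Tnf 1.65 ± 0.53 did not pass. Nor did Il1b -1.40 ± 1.6, Cxcl2 1.31 ± 0.62, Nos2 0.11 ± 2.21 and Cxcl10 0.05 ± 0.74. Nor did Fos 3.38 ± 0.63, Nfkbia 1.23 ± 0.18, Egr1 0.83 ± 0.38 and Tnfaip3 0.00 ± 0.28. Nor did H3f3b -0.35 ± 0.18, H3f3a -0.30 ± 0.32, Setd2 -0.14 ± 0.14, Chuk -0.09 ± 0.15 and Zmynd11 -0.08 ± 0.18. Nfkbia had an adjusted p of 0.017 with the replicate block. Il6 stood at 24.5 normalized reads in RAW264.7 at 60 min and 0.432 and 0.642 in lines 264 and 3205. Its adjusted p was 0.18 and 0.44 for the difference. As groups, cytokines and chemokines rose less in line 264 (median difference -0.67, 22 of 28 genes below 0, 3 lower adjusted over the list alone, camera adjusted p = 6.4e-09, 0.035 with an estimated correlation, 0.0621 with a replicate block too). So did NF-kB genes (-0.27, 3 lower adjusted over the list alone, 1.4e-05, 0.026 with an estimated correlation, 0.0579 with the block too), and fry gave 0.063 for both. The genes induced in primary macrophages by the authors' deposited table had a median of -0.48, with 129 of 179 below 0 and 3 higher and 12 lower adjusted over the list alone (1.5e-16, 0.026, 0.0448 with the block too). In line 3205 the cytokine median was -0.84 (2 lower adjusted over the list alone, 9.2e-06, 0.15 with an estimated correlation). The secondary response median was -0.78 (1, 2.6e-05, 0.47), against -0.79 in line 264 (2, 0.00074, 0.44). The chemokine gene Ccl5 stood at -3.08 ± 0.56 and -3.61 ± 0.56 in lines 264 and 3205 without passing. Its limma adjusted p was 0.3 and 0.18 (0.048 in line 3205 with the replicate block). In all, 1 gene was higher and 2 lower in line 264 (8 and 14 with a replicate block). By edgeR 4 and by DESeq2 25 were called in all. In line 3205, 0 were higher and 1 lower (6 and 8 with the block). There edgeR and DESeq2 called 1 and 21. The 3 calls of line 264 became 0 without any 1 of 7 libraries and 1 without line 264 60 min replicate 2. In line 264 Txnip (adjusted p 0.08 to 0.37) and Rasgef1b (0.069 to 0.35) failed without any 1 of the 8 libraries. Bhlhe40 failed without any library but line 264 60 min replicate 2. In line 3205 Bhlhe40 (adjusted p 0.054 to 0.19) failed without any 1 of the 8 libraries.

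At 120 min the MAP kinase phosphatase gene Dusp1 responded less in both lines. The limma difference was -3.85 ± 0.30 in line 264 (adjusted p = 0.0036) and -3.95 ± 0.30 in line 3205 (adjusted p = 0.0028). Its mean rose from 222 to 12660 normalized reads in RAW264.7, from 224 to 900 in line 264 and from 897 to 3288 in line 3205. At 60 min its mean was 10209, 2192 and 8915 in the same order. Rasgef1b went from 1183 to 11456 in RAW264.7 and from 5848 to 5858 in line 264 (limma difference -3.23 ± 0.32, adjusted p = 0.016). The exchange factor gene Iqsec1 fell from 1982 to 497 in RAW264.7 and stood at 4121 and 4159 in line 264 (limma, 2.0 ± 0.24, adjusted p = 0.035). In line 3205, without calls, Rasgef1b went from 7240 to 9882 and Iqsec1 from 3453 to 2837. The sphingomyelin synthase gene Sgms2 reached 119 normalized reads in RAW264.7 at 120 min and was at or below 2.62 in the other 8 groups (limma adjusted p = 0.016 in line 264). No gene of the fixed panel passed in line 264. Il1b -3.53 ± 1.86, Ifnb1 -3.04 ± 1.63 and Ccl4 -1.54 ± 0.88 did not pass. Nor did Tnf -1.30 ± 0.57, Cxcl10 1.02 ± 0.94, Cxcl2 0.70 ± 0.59 and Nos2 0.25 ± 2.11. Nor did Fos 2.78 ± 0.61, Egr1 1.19 ± 0.44, Tnfaip3 -0.95 ± 0.28 and Nfkbia -0.21 ± 0.19. Nor did H3f3a -0.27 ± 0.37, H3f3b 0.19 ± 0.21, Zmynd11 -0.13 ± 0.16, Chuk 0.09 ± 0.16 and Setd2 -0.03 ± 0.18. In line 3205 none passed. Il1b -3.31 ± 1.86, Cxcl2 2.13 ± 0.59 and Nos2 1.75 ± 2.11 did not pass. Nor did Ccl4 -0.96 ± 0.88, Ifnb1 -0.77 ± 1.63, Tnf 0.70 ± 0.57 and Cxcl10 0.38 ± 0.94. Nor did Fos 2.10 ± 0.61, Egr1 0.96 ± 0.44, Tnfaip3 -0.73 ± 0.28 and Nfkbia 0.48 ± 0.19. Nor did H3f3a -0.79 ± 0.37, H3f3b -0.46 ± 0.21, Chuk 0.05 ± 0.16, Setd2 -0.05 ± 0.18 and Zmynd11 0.03 ± 0.16. Il6 reached 1375 and 584 reads in RAW264.7, 159 and 26 in line 264 and 48 and 13 in line 3205. Its adjusted p was 0.68 and 0.27 for the difference (0.031 in line 3205 with the replicate block). Interferon-stimulated genes had median differences of -1.02 in line 264 and -1.89 in line 3205 over 35 genes. Of them 34 were below 0 in each line (0 and 2 lower adjusted over the list alone). Camera adjusted p was 5.3e-12 and 2.9e-21, and 0.58 and 0.51 with an estimated correlation. Among list members, Il10 (limma, -3.23 ± 0.78, adjusted p = 0.55) and Cxcl9 (0.61) did not pass in line 264. Nor did Malt1 (-2.38 ± 0.39), Ifih1 (-3.47 ± 0.84) and the histamine gene Hdc (-4.98 ± 0.72) in line 3205. Their adjusted p was 0.14, 0.44 and 0.1 (0.0071, 0.014 and 0.007 with the replicate block). In all, 1 gene was higher and 3 lower in line 264 (11 and 34 with a replicate block). By edgeR 2 and by DESeq2 52 were called in all. In line 3205, 0 were higher and 1 lower (50 and 69 with the block). There edgeR and DESeq2 called 3 and 91. The 4 calls of line 264 became 0 without RAW 120 min replicate 1, 2 without RAW 120 min replicate 2 and 1 without any other library. The 1 call of line 3205 became 4 without RAW 120 min replicate 2 and 2 without line 3205 120 min replicate 2. In line 264 Iqsec1 (adjusted p 0.082 to 0.32) and Sgms2 (0.054 to 0.15) failed without any 1 of the 8 libraries. Dusp1 failed without RAW 120 min replicate 1, and Rasgef1b without any library but RAW 120 min replicate 2. Dusp1 in line 3205 kept its call without any 1 of the 8 libraries.

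**Figure D3:**
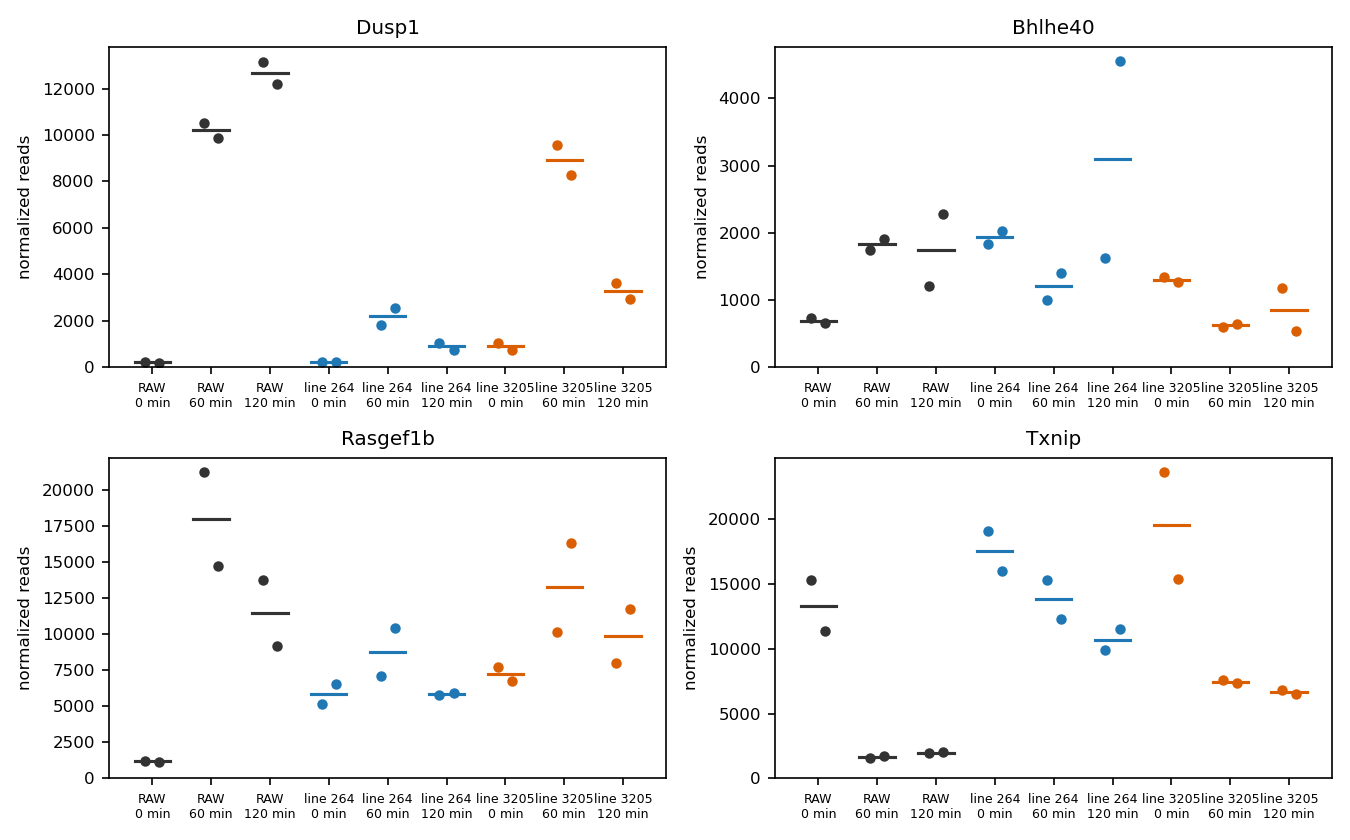
Normalized reads of Dusp1, Bhlhe40, Rasgef1b and Txnip in each of the 18 libraries by cell line and minutes of LPS; points are libraries and bars the mean of 2. Dusp1 at 120 min reached a mean of 12660 in RAW264.7, 900 in line 264 and 3288 in line 3205.

 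The genes induced in primary macrophages by the authors' deposited table also rose in the cell lines. In RAW264.7 they rose at 99 of 179 at 60 min and 130 of 181 at 120 min (133 and 147 adjusted over the list alone, adjusted p = 0.00023 and 0.0021 with an estimated correlation). In line 264 the counts were 60 and 109 and in line 3205 71 and 102. The 6 genes lowered in the authors' deposited table had a median of -1.26 in line 264 at 60 min, with 1 call and 3 adjusted over the list alone (adjusted p = 0.22 with an estimated correlation). Beyond these induced genes and the immediate early, cytokine, NF-kB, secondary response, lysosome and macrophage identity genes, no fixed list passed with an estimated correlation. With the preset correlation, other lists besides interferon-stimulated genes had calls. Replication-coupled histone H3 genes (adjusted p = 0.006, 0.51 with an estimated correlation) were called in the line 3205 response difference at 120 min. Dendritic cell markers (0.029, 0.51) were called there too. Neutrophil markers (0.0058; 0.27) were called in line 3205 against RAW264.7 at 120 min, and osteoclast markers (0.021; 0.68) in line 264 against RAW264.7 at 120 min. TLR4 signalling components (0.0069; 0.055) stood at 5 higher and 2 lower of 29 in line 264 at 120 min. Housekeeping genes (0.017; 0.097) stood at 1 higher of 17 in line 264 at 60 min, and H3.3 deposition and readout genes (0.019; 0.23) at 1 higher of 22 in line 3205 at 60 min. Glycolysis and hypoxia genes, mitochondrially encoded genes and erythroid and megakaryocyte markers passed in no comparison, with lowest adjusted p of 0.115, 0.156 and 0.308. With the replicate block the lowest was 0.038 for glycolysis and 9.4e-08 for mitochondrially encoded genes, in the response difference of line 264 at 120 min.

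The test in the authors' deposited table asks for a change beyond a log2 fold change of 1, which gave back the p-values of all 10 comparisons to within 3.4e-06. By the authors' deposited table, 96 genes rose and 8 fell in RAW264.7 at 60 min, 67 and 3 in line 264, and 74 and 1 in line 3205, and at 120 min 221 and 83, 166 and 32, and 160 and 32.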

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

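The tests of the edit apart from clone history and of ChIP library scaling were chosen only after the result was seen, and TMM was added after the data were seen. The response to LPS differed from that of RAW264.7 by an interaction test in limma for the following genes (adjusted p, then adjusted p with the replicate block). In line 264 at 60 min these were Txnip (2.68 ± 0.31; 0.035, 0.0031), Rasgef1b (-3.33 ± 0.38; 0.035, 0.012) and Bhlhe40 (-2.10 ± 0.23; 0.035, 0.0053). In line 3205 Bhlhe40 differed by -2.46 ± 0.23 (0.016, 0.0023). At 120 min in line 264 they were Dusp1 (-3.85 ± 0.30, 0.0036, 6.5e-06), Rasgef1b (-3.23 ± 0.32, 0.016, 0.0027) and Iqsec1 (2.0 ± 0.24, 0.035, 0.0024). Sgms2 was near 0 reads in all groups but 1, so its fitted difference of -7.70 ± 0.80 (0.016, 0.0053) depends on the pseudocount. In line 3205 Dusp1 differed by -3.95 ± 0.30 (0.0028, 5e-06) and kept its call without any 1 library. In line 264 Dusp1 did not pass without RAW 120 min replicate 1 (0.058). The other 7 calls each failed without most or all of the 8 libraries. No biological explanation beyond the line itself was tested for these genes.

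More than 2000 genes differed between each edited line and RAW264.7 before LPS. Genes near the detection limit do not account for this, since 19.7% of the calls in line 3205 and 18.8% in line 264 lay below 50 normalized reads. Altered copy number of chromosome segments stays open. Among genes of known position with at least 50 normalized reads, 19.3% of calls (18.6% in line 264) lay inside segments shifted in the direction of the call. This is between the bounds set beforehand, and windows of 51 genes miss focal changes. Segments shifted in either direction held 8.1% and 7.8% of all such genes, a measure that asks for no direction. Expressed genes were higher on chromosome 1 in both lines (medians 0.44 and 0.42), 19 in line 264 (0.51) and 15 in line 3205 (0.52), and at later times the lowest share of such genes was 73.3%, short of the 75% asked for; without DNA, copy number and regulation cannot be told apart there. Loss of H3.3 likewise cannot be told apart from clone history, as each edit is 1 line, and 50 genes were called in opposite directions in the 2 lines.

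Interferon-stimulated genes had median response differences from RAW264.7 of -1.02 and -1.89 at 120 min, but 0 and 2 of 35 passed adjusted over the list alone. The list did not pass with an estimated correlation between its genes (adjusted p 0.58 and 0.51), so a weaker response of the group is not established. Scaling of the deposited values was excluded as the source of these medians, since the median closest to 0 after TMM or quantile normalization was -0.98. An origin in 1 replicate number was excluded too, since the difference within a replicate number was -1.22 or lower in both lines.

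ChIP signal of H3S31ph, H3S28ph and H3.3 was higher at 60 min at nearly all listed genes of primary macrophages. Library scaling, which would lift all genes alike, was excluded as the whole cause for H3S31ph, where the 6 genes whose RNA fell differed from the induced genes by -1.56 on the log2 scale (medians 0.40 and 1.96). For H3S28ph the distance was -0.46 (0.92 and 1.37), between the bounds, so scaling and a gain at induced genes cannot be told apart. For H3.3 it was 0.08 (1.04 and 0.96), so its rise may be scaling alone. A gain of H3S31ph with induction is a hypothesis that rests on 1 library per time.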

How the results depend on the processing

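Choices were made before the data were examined unless stated. Of 538 gene results picked for the text, 290 kept their direction and their side of the threshold in every setting and without any 1 library. Across settings they gave 5064 values on the same side, 193 that no longer passed, 92 that newly passed and 19 that changed sign. Without 1 library the numbers were 2142, 236, 12 and 98. Of the 193 losses 133 came with only the groups compared in the fit and 32 by limma without trend, and the replicate block gave 28 of the gains and none of the losses. Lists tested for response differences kept their result in 61 values and lost the call in 84 across settings, and in 181 and 49 without 1 library. On simulated data with the spread between these replicates, limma found 41% of 2-fold and 90.0% of 4-fold changes in the RAW264.7 response at 60 min. For response differences it found 5% to 11% and 62% to 78%. With the smaller spread left after the replicate block it found 43% to 58% and 92% to 97% of them. ChIP had 1 library per target and time, and its spread between cultures could not be measured. Alternatives set beforehand but not run were median-ratio and upper quartile factors (the values were already scaled), division by input (no input values in the files) and another ChIP pseudocount (none was used).

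The order within each time is RAW264.7, line 264 and line 3205, or line 264 and line 3205, unless a line is named. edgeR, DESeq2, TMM scaling and the list test with both a block and an estimated correlation were added after the data were seen. The cause was not tested unless given. With a replicate block counts for the responses were 1398, 691 and 691 at 60 min and 4137, 2859 and 2496 at 120 min. Those of the lines against RAW264.7 were 4037 and 4581 at 0 min, 4648 and 4833 at 60 min and 4415 and 4753 at 120 min. Those of the response differences were 22 and 14 at 60 min and 45 and 119 at 120 min. By edgeR with a replicate block counts for the responses were 1286, 808 and 789 at 60 min and 4070, 3035 and 2825 at 120 min. Those of the lines against RAW264.7 were 4088 and 4577 at 0 min, 4363 and 4637 at 60 min and 4151 and 4694 at 120 min. Those of the response differences were 15 and 15 at 60 min and 33 and 101 at 120 min. With only the groups compared in the fit, which leaves fewer samples, counts for the responses were 88, 7 and 11 at 60 min and 934, 0 and 18 at 120 min. Those of the lines against RAW264.7 were 971 and 884 at 0 min and 1056 and 1117 at 120 min. Those of the response differences were 0 in line 264 at 60 min and 1 and 2 at 120 min. By DESeq2 counts for the responses were 850, 504 and 501 at 60 min and 1792 and 1671 in lines 264 and 3205 at 120 min. Those of the response differences were 25 and 21 at 60 min and 52 and 91 at 120 min. By edgeR counts for the response differences were 2 and 3 at 120 min. With an absolute log2 fold change of at least 1 asked for, which keeps fewer genes by construction, counts for the responses were 1122, 588 and 554 at 120 min. Those of the lines against RAW264.7 were 1429 and 1530 at 0 min, 1620 and 1585 at 60 min and 1601 in line 3205 at 120 min. By limma without trend counts for the responses were 625 and 548 in lines 264 and 3205 at 120 min. Those of the response differences were 1 and 2 at 60 min and 6 in line 3205 at 120 min. With a pseudocount of 5 counts for the response differences were 6 in line 264 at 60 min and 14 and 8 at 120 min. With no filter on low values counts for the response differences were 0 in line 264 at 60 min and 5 in line 3205 at 120 min. The replicate block changed the call of no named gene beyond those given beside the results. With the preset correlation it ended list calls of replication-coupled histone H3 genes in the RAW264.7 and line 264 responses at 60 min (adjusted p = 0.0568 and 0.0614) and of TLR4 signalling components and housekeeping genes in that of line 3205 (0.0576 and 0.0593). It also ended those of neutrophil markers in line 3205 against RAW264.7 at 0 min (0.0565), line 264 against RAW264.7 at 120 min (0.0719) and its response difference then (0.0503), and of LPS-lowered genes in line 3205 against RAW264.7 at 60 min (0.0512). It added calls, all at 0.0492 or lower, of mitochondrially encoded, glycolysis, cell cycle, p53, TLR4 and stress response lists.

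Without 1 library in turn, where the lone sample left in a group is assumed to vary like the other groups, all but 1 result counted fewer genes at its lowest value, with fewer samples in the fit. Counts of the responses ran from 179 to 247, 109 to 151 and 104 to 167 at 60 min and 671 to 981, 348 to 586 and 323 to 683 at 120 min. Those of the lines against RAW264.7 ran from 1199 to 1705 and 1226 to 2348 at 0 min, 1487 to 1571 and 1407 to 1562 at 60 min and 1169 to 1561 and 1109 to 1602 at 120 min. Those of the response differences ran from 0 to 1 in line 264 at 60 min and 0 to 2 and 1 to 4 at 120 min. The call of line 3205 at 60 min became 0 without any of its libraries. Lists called in the response differences (264 and 3205 at 60 min, then at 120 min) numbered 3, 0, 0 and 0 with an estimated correlation, 0, 0, 1 and 0 by fry and 1, 0, 0 and 0 with a block and an estimated correlation. Without 1 library they ran from 5 to 12 and 4 to 12 at 120 min. Cell cycle genes ran from an adjusted p of 5.33e-14 to 0.5 in line 3205 at 60 min, and cholesterol biosynthesis from 4.71e-07 to 0.941 at 120 min, with 1 reversal of direction each.

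Log2 fold changes that changed sign under a setting belonged to panel genes that did not pass in that comparison. For the line 264 response at 60 min, Il6 -0.13 (edgeR, edgeR with block) and -0.14 (DESeq2). For the line 3205 response at 60 min, Setd2 0.02 (TMM). For line 264 against RAW264.7 at 60 min, Tnf 0.02 (TMM). For line 3205 against RAW264.7 at 60 min, Il1b 0.39 (edgeR, DESeq2). For line 264 against RAW264.7 at 120 min, Zmynd11 0.02 (TMM). For the line 3205 difference at 60 min, Cxcl10 -0.04 (edgeR with block) and -0.01 (DESeq2), Tnfaip3 0.00 (pseudocount 5), Nos2 -0.10 (edgeR, edgeR with block) and -0.06 (DESeq2). For the line 264 difference at 120 min, Setd2 0.00 (TMM), Nos2 -0.08 (edgeR with block) and -0.01 (DESeq2). For the line 3205 difference at 120 min, Setd2 0.02 (edgeR, edgeR with block).

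Without 1 library in turn these panel genes, none of them called, took both signs. For the RAW264.7 response at 60 min, H3f3a -0.22 to 0.29. For the line 264 response at 60 min, H3f3a -0.29 to 0.10, Il6 -0.45 to 0.45, Setd2 -0.12 to 0.00, Nos2 -1.91 to 1.43 and Zmynd11 -0.02 to 0.17. For the line 3205 response at 60 min, Setd2 -0.05 to 0.05, Nos2 -0.95 to 3.28 and Zmynd11 -0.06 to 0.11. For the RAW264.7 response at 120 min, H3f3a -0.09 to 0.42. For the line 264 response at 120 min, H3f3a -0.27 to 0.06 and Zmynd11 -0.16 to 0.01. For the line 3205 response at 120 min, Zmynd11 0.00 to 0.15. For line 264 against RAW264.7 at 0 min, Il1b -0.57 to 1.53, Setd2 -0.08 to 0.04, Nos2 -1.09 to 2.25 and Tnf -0.60 to 0.14. For line 3205 against RAW264.7 at 0 min, Il1b -0.33 to 3.02, Ifnb1 -0.47 to 0.80, Setd2 -0.08 to 0.03 and Nos2 -1.08 to 3.15. For line 264 against RAW264.7 at 60 min, Nos2 -1.47 to 0.04, Fos -1.0 to 0.41, Zmynd11 -0.01 to 0.17 and Tnf -0.08 to 0.06. For line 3205 against RAW264.7 at 60 min, Il1b -1.26 to 1.14, Nos2 -0.46 to 2.75 and Nfkbia -0.04 to 0.15. For line 264 against RAW264.7 at 120 min, Ifnb1 -4.37 to 0.17, Cxcl10 -2.21 to 0.20, Nos2 -0.30 to 1.96, Zmynd11 -0.04 to 0.01 and Egr1 -0.48 to 0.25. For line 3205 against RAW264.7 at 120 min, Setd2 -0.23 to 0.08 and Fos -0.99 to 0.15. In the line 264 difference at 60 min, H3f3a -0.38 to 0.13, Cxcl2 -0.23 to 1.13, Cxcl10 -0.65 to 1.27, Nos2 -2.96 to 0.37, H3f3b -0.07 to 0.27, Zmynd11 -0.12 to 0.06, Tnf -0.16 to 0.59 and Chuk -0.09 to 0.02. In the line 3205 difference at 60 min, Il1b -3.08 to 0.27, Cxcl10 -0.48 to 0.59, Tnfaip3 -0.17 to 0.17, Nos2 -2.0 to 2.22, Zmynd11 -0.17 to 0.01 and Chuk -0.20 to 0.02. In the line 264 difference at 120 min, Cxcl10 -0.18 to 2.23, Setd2 -0.08 to 0.03 and Nos2 -1.42 to 1.92. In the line 3205 difference at 120 min, Cxcl10 -0.16 to 0.91, Setd2 -0.20 to 0.10, Nos2 -0.36 to 3.87, Zmynd11 -0.05 to 0.10 and Chuk -0.06 to 0.15.

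ChIP medians (log2) became 1.06 for H3S31ph, 0.46 for H3S28ph, -0.56 for H3K27ac, -0.20 for H3K36me3 and -0.97 for H3K36me2 once divided by the H3.3 signal. That construction removes the H3.3 rise, so it reverses the direction of H3K27ac, H3K36me3 and H3K36me2. Without genes of low signal H3K36me2 had a median of -0.02 and a correlation with RNA of -0.05, and by Pearson r H3S31ph correlated at 0.42. The other 21 ChIP values under alternatives moved less than their interval.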

Other observations

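All tests in this part but the camera test were set before their result was seen, and the patterns behind them were found in the same data. A hypothesis was that H3S31ph gain marks the genes that depend on H3.3, so that genes with a larger H3S31ph ratio in primary macrophages would respond less to LPS in the edited lines. Over 176 genes at 60 min the Spearman correlation between ratio and response difference was -0.01 in line 264 and 0.02 in line 3205, and over 178 genes at 120 min -0.06 and -0.02. The lowest, -0.06, was above the bound of -0.1, so no such ranking was seen. The ratio ranked with the RAW264.7 response at only 0.22 and 0.17 (60 and 120 min). Primary cells and cell lines also differ, so the hypothesis stays open.

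Genes with names beginning in Zfp fell together at 60 min of LPS, with medians over 293 genes of -0.41 in RAW264.7, -0.35 in line 264 and -0.39 in line 3205. At 120 min the medians were -0.32, -0.25 and -0.20. A chance draw of genes of like abundance was tested at 60 min, where 0 of 10000 random lists reached as low in any line, and at 120 min, where 11 did in line 3205. Random lists take genes as independent, and the family was picked after members stood among the largest decreases, so that bound was too weak and a shared fall stays a hypothesis. Camera with an estimated correlation gave adjusted p of 0.062, 0.024 and 0.027 at 60 min (0.015, 0.0051 and 0.0056 with the replicate block) and 0.25, 0.45 and 0.50 at 120 min. At 60 min 34, 25 and 17 of them were called lower by limma and 9, 6 and 5 higher.

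The mitochondrial share of reads was 0.22% to 0.62% in replicate 1 and 1.16% to 1.70% in replicate 2 of the cell line libraries. The response of interferon-stimulated genes at 120 min had a median of 2.56 in replicate 1 and 1.42 in replicate 2 of RAW264.7, 0.99 and 0.05 in line 264, and 0.46 and -0.31 in line 3205.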
